A study of Homo sapiens with 15 samples.

How the data were processed

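The series holds 15 Affymetrix arrays of human PBMCs in 3 groups of 5, taken before exercise, at the end of exercise and after 1 h of recovery. Per the labels, each sample combined PBMCs from 3 donors, RNA was extracted on RNeasy columns, and targets were made by the array maker's standard procedures from about 10 ug of total RNA. Groups and pool numbers were taken from the labels. The deposited values are linear intensity values per probe set. The software and scaling behind them are not given in the sources used here, and the labels give no scan date or batch.

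The table held 22215 probe sets, and 0.161% of its values were at or below 0. The log2 trimmed means (2% trimmed) of the arrays lay within 0.09 of each other, under the limit of 0.2 set before the data were examined, so the deposited scaling was kept. Values below the 20th percentile of the table (97.1) were set to it before taking log2, so the changes of weakly expressed genes are understated. In the platform annotation, 19065 probe sets had 1 gene symbol, 1043 had several and 2107 were not listed. Of those with 1 symbol, 19053 were found in the RefSeq gene table (GRCh38.p14), which was used for names only, and 0 symbols needed updating. XIST and Y-linked probe sets (32) were left out. Each gene was represented by its probe set with the highest mean over all arrays. Of 11939 genes, those with a mean log2 value under 7.51, the 40th percentile of all probe sets, were left out, which left 8147.

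Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) as a model of 3 group means over all 15 arrays, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The median within-group SD was 0.14 on the log2 scale. The labels do not say whether pools came from separate donors, so p-values measure the spread between these samples. Of 34 gene lists fixed before the data were examined, 33 had at least 5 genes tested and were tested with camera at a preset correlation of 0.01, adjusted over lists and comparisons together (99 tests). The calls that held with an estimated correlation were NK cells in the first comparison, classical monocytes and glucocorticoid-induced genes in the second, and NK cells and classical monocytes in the third. fry was run as a further alternative. Some lists share genes, so their calls are not independent. S100A12 and CD14 are in both the classical monocyte list and the IL-1 and Toll-like receptor list. As fixed, CD163 is in both the classical monocyte and the glucocorticoid-induced list. IL1R2 is in both the glucocorticoid-induced list and the IL-1 and Toll-like receptor list. DUSP1 is in both the immediate early and the glucocorticoid-induced list.

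Genes were named by a rule fixed beforehand: the 10 largest rises and 10 largest falls among called genes of each comparison, and up to 4 members with the smallest p of each list described. The genes called at both times were named because they were few, and 3 markers of mature neutrophils because they were called in a comparison. All of these were named after their values were seen.

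The comparison of the end of exercise with before exercise was simulated 20 times (8147 genes, 200 of them changed). Of genes changed 1.25-fold 44.3% were called, of those changed 1.5-fold 94.6% and of those changed 2-fold 99.3%, with 4.52% false discoveries. Noise was drawn independently for each gene and array. These shares therefore need not hold for the data, where genes are correlated and pool numbers pair arrays.

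Whether pool numbers pair the arrays was checked by correlating deviations from the group means. Between 1 h of recovery and before exercise the same-number correlations were 0.337 to 0.572, all over 0.1, and each of the 10 arrays correlated best with its own number. The numbers therefore pair these groups by the data, while the labels do not state it. For the other comparisons 1 of the 5 correlations was under 0.1.

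For arrays shared by 2 comparisons (those before exercise, and those at the end of exercise), unchanged groups were simulated in 100 draws as independent arrays with the pooled residual covariance. A first version that permuted residual arrays was discarded, because residuals sum to 0 within a group and 1 draw gave a correlation of exactly 1. A further 100 draws correlated arrays of the same pool number by the median same-number correlation of each pair of groups. The alternatives were other scalings, floors, filters, probe set rules, variance models, array weights, the pool number as a block or random effect, a threshold of 0.001 without adjustment, and leaving out each array. Splitting the arrays at the end of exercise between the comparisons that share them was added after seeing the data, as were tests of list scores within pool numbers. Intensities of probe sets with several genes or none listed entered no named result.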

Results

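Gene expression was measured on Affymetrix oligonucleotide arrays in peripheral blood mononuclear cells (PBMCs), the blood fraction that holds lymphocytes, natural killer (NK) cells and monocytes. Blood was taken before exercise, at the end of exercise and after 1 h of recovery. Each of the 3 groups held 5 arrays, and per the labels each array was hybridised with RNA from the cells of 3 donors. The labels give no kind or intensity of exercise and no group of unexercised donors. The table held 22215 probe sets for each of the 15 arrays, with median intensities from 230.0 to 244.4. After filtering, 8147 genes were tested. The number of arrays limited the precision: the median standard error of a difference between 2 groups was 0.091 on the log2 scale. Nothing in the labels says whether pools with the same number in different groups came from the same donors.

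The first comparison asked which transcripts differed at the end of exercise from those before it. The clearest rise was in genes of NK cells and cytotoxic lymphocytes. GZMB, which encodes the granule protease granzyme B, rose by 1.53 ± 0.12 (log2, SE, 5 arrays per group), a 2.89-fold increase, and the NK cell receptor gene CD160 rose by 1.56 ± 0.20. The largest rise was that of DUSP2, a phosphatase of MAP kinases, at 2.13 ± 0.15 or 4.39-fold. The B cell genes BANK1 and TCL1A were among the largest falls. In the limma fit, 285 genes were higher and 105 lower at the end of exercise (Benjamini-Hochberg adjusted p under 0.05), and 40 of the higher genes changed at least 2-fold.

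After DUSP2, the largest rises were those of the chloride channel gene CLIC3 (1.92), the aldo-keto reductase gene AKR1C3 (1.82), KIR2DL2 (1.66) and the cAMP-responsive transcription factor gene CREM (1.58). They were followed by CD160, the serine protease gene PRSS23 (1.54), GZMB, KIR2DS2 (1.53) and the chemokine gene CCL4 (1.52). The KIR genes are near-identical to each other, so the values of KIR2DL2 and KIR2DS2 are uncertain as to the member measured. The largest falls were those of the transcription factor gene MYC (-0.80), BANK1 (-0.72), TCL1A (-0.72), the potassium channel gene KCNJ2 (-0.70) and the purinergic receptor gene P2RY13 (-0.68). HK3 (-0.64), H2AX (-0.64), FCGR1BP (-0.59), CYP1B1 (-0.58) and NAIP (-0.57) fell less. FCGR1BP is a close copy of other Fc receptor genes, and its value is uncertain for the same reason. Each of these 20 genes moved in its direction in 5 of 5 pool numbers, which their choice as the largest called changes made likely. HK3 lost its call in 1 of the 15 fits that left out 1 array.

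Of 18 tested cytotoxic granule and effector genes, 13 rose and none fell, and 14 rose when adjusted over the list alone. GNLY, encoding granulysin, rose by 1.24, the transcription factor gene TBX21 by 1.22 and CST7 by 1.37. The list was called up by camera with a preset correlation, and its adjusted p = 0.0827 with an estimated correlation. Of 10 NK cell markers, 6 rose and 7 rose when adjusted over the list alone, among them KLRF1 (1.33), KLRD1 (1.24) and the chemokine gene XCL1 (1.38). The NK cell list had an adjusted p = 0.0265 with an estimated correlation, and its mean change was 0.70 ± 0.08. Of 7 tested markers of mature neutrophils, a cell type that PBMC preparations can carry over, CXCR2 (0.97) and FCGR3B (0.91) also rose and CSF3R (-0.45) fell, with the same counts adjusted over the list alone. These 3 genes were named after their values were seen, the FCGR3B probe set can share signal with FCGR3A of NK cells, and CSF3R lost its call in 9 of the 15 fits that left out 1 array. The neutrophil list had a mean change of 0.23 ± 0.03 and a median of 0.08, was not called by camera (adjusted p = 0.068 at the preset correlation and adjusted p = 0.246 with an estimated correlation) and was called up by fry (adjusted p = 0.000476).

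Of 14 classical monocyte markers, 4 fell, and 9 fell when adjusted over the list alone. The members with the smallest p were MNDA (-0.35), the chemokine receptor gene CCR2 (-0.41), S100A9 (-0.25) and VCAN (-0.27), and the list had an adjusted p = 0.104 with an estimated correlation. Of 15 B cell markers 3 fell, which were TCL1A, BANK1 and FCER2 (-0.34), against 5 adjusted over the list alone. That list had an adjusted p = 0.273 with an estimated correlation. Of 10 genes of naive and central memory T cells 3 fell, which were NELL2 (-0.53), CCR7 (-0.32) and LEF1 (-0.32), and 4 fell when adjusted over the list alone (adjusted p = 0.0827 with an estimated correlation). Of 13 T cell markers, UBASH3A (-0.41) and CD28 (-0.34) fell, with 3 lower and 1 higher adjusted over the list alone. The T cell list had an adjusted p = 0.618 with an estimated correlation. Of the 15 fits that left out 1 array, the call was lost in 11 for FCER2, 7 for UBASH3A, 6 for CD28, LEF1, S100A9 and VCAN, 5 for MNDA and 4 for CCR2.

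Of 24 immediate early genes, which respond within minutes to many stimuli, 6 rose and 1 fell, with 9 and 2 adjusted over the list alone. CD69, an early activation antigen of lymphocytes, rose by 1.49 and the phosphatase gene DUSP1 by 1.24, whereas MYC was the member that fell. This list had an adjusted p = 0.262 with an estimated correlation. Of 14 glucocorticoid-induced genes 5 rose, including DDIT4 (1.29), ZBTB16 (1.03) and CXCR4 (0.60), with 5 higher and 2 lower adjusted over the list alone (adjusted p = 0.249 with an estimated correlation). Of 11 circadian clock genes 4 rose, and 5 adjusted over the list alone. They were NFIL3 (0.60), BHLHE40 (0.93), RORA (0.42) and CLOCK (0.36), and the list had an adjusted p = 0.173 with an estimated correlation. Of 14 heat shock chaperones 2 rose, DNAJB1 (0.97) and DNAJA1 (0.53), and 3 adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). Of 13 genes of the IL-1 and Toll-like receptor pathway 3 fell, IRAK3 (-0.55), TLR5 (-0.28) and TLR1 (-0.47), while IL18RAP rose by 1.10. Adjusted over the list alone 7 fell and 1 rose, and the list had an adjusted p = 0.333 with an estimated correlation. The call was lost in 7 of the 15 fits that left out 1 array for RORA and CLOCK, 6 for TLR1, 4 for IRAK3 and 3 for TLR5. For the lists of this paragraph, neither a shift in cell mix nor the time of day was tested as a cause at the end of exercise. Relative to before exercise, the circadian list averaged 0.26 at the end and -0.07 at recovery, and the NK cell list 0.70 and -0.26.

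**Figure D1:**
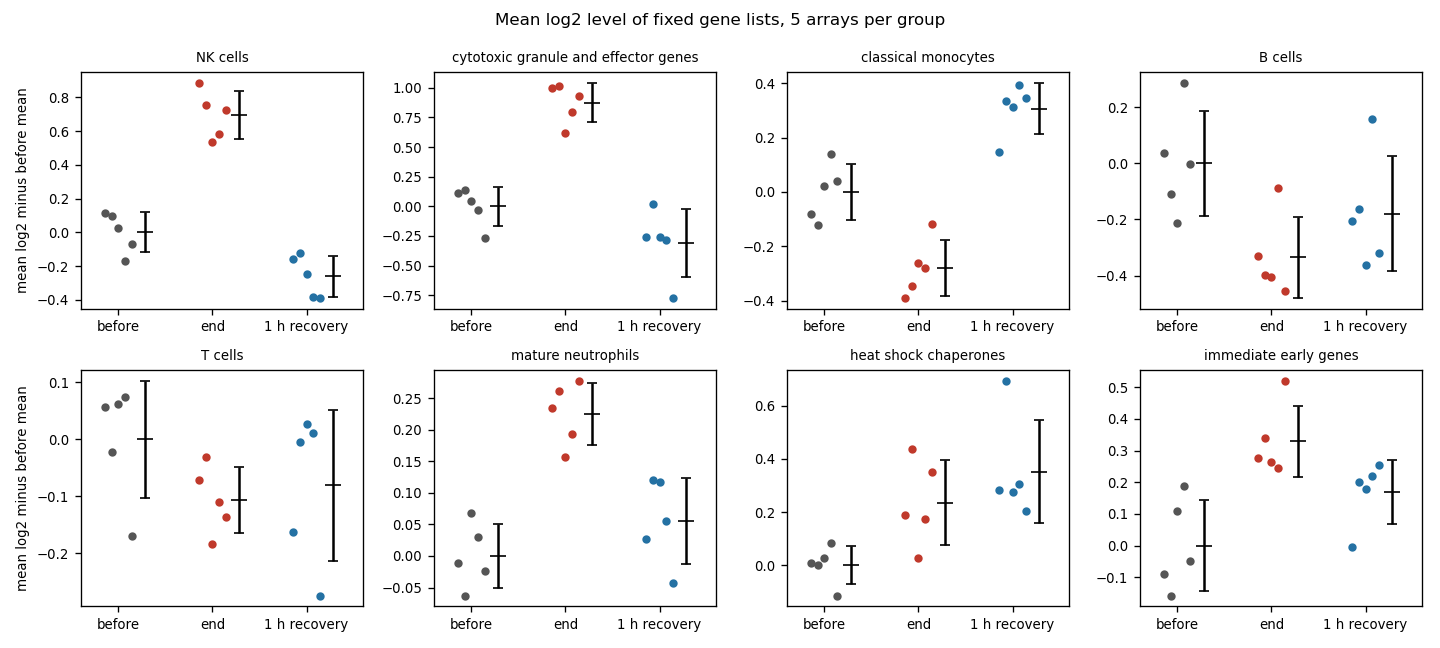
Mean log2 level of the tested members of 8 gene lists in each array (points), relative to the mean of the 5 arrays before exercise, with group means and SD (bars). The NK cell list averaged 0.70 above its level before exercise at the end of exercise, and the classical monocyte list 0.31 above it after 1 h of recovery.

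The second comparison asked which transcripts still or newly differed after 1 h of recovery from those before exercise. The genes HSPH1 and CREM and a few members of the classical monocyte list were higher. HSPH1, a chaperone of the heat shock response, had risen by 1.05 ± 0.19 (log2, SE, 5 arrays per group) or 2.08-fold, and CREM by 0.93 ± 0.13. Among members of that list, which need not be particular to monocytes, FPR1, the receptor for bacterial formyl peptides, had risen by 0.74 ± 0.12. In the limma fit, 18 genes were higher and 2 lower (adjusted p under 0.05).

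The other large rises were those of the pseudokinase gene TRIB1 (0.79), the glutaminyl cyclase gene QPCT (0.77), CYP1B1 (0.75), RGS2 (0.71), VNN2 (0.57), the chemokine receptor gene CCR1 (0.57) and the transcription factor gene HLX (0.55). The genes that fell were CLK4 (-0.50), a kinase of splicing factors, and IL2RB (-0.44), a receptor chain for interleukin 2 and interleukin 15. Of 14 classical monocyte markers 3 rose, which were FPR1, S100A12 (0.53) and CCR2 (0.52), and 11 rose when adjusted over the list alone. The list had an adjusted p = 0.0265 with an estimated correlation, and all 14 members had a positive change. Of 7 tested markers of mature neutrophils none passed the test over all genes, with a median change of 0.07. CSF3R had a value of 0.41 and FCGR3B of -0.41, and the others lay between 0.02 and 0.14.

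Of 14 heat shock chaperones HSPH1 rose, and 10 rose when adjusted over the list alone. STIP1 had a value of 0.50 (adjusted p = 0.0514), HSPB1 of 0.75 and FKBP4 of 0.53. The heat shock list had an adjusted p = 0.0893 with an estimated correlation. At 1 h of recovery the mean of the list lay 0.70 above the level before exercise in pool 2 and 0.20 to 0.31 above it in the other 4 pools. Of 14 glucocorticoid-induced genes none passed over all genes and 4 rose when adjusted over the list alone. DUSP1 had a value of 0.85, TSC22D3 of 0.33 and SGK1 of 0.65, and the list had an adjusted p = 0.0265 with an estimated correlation. Of 13 genes of the IL-1 and Toll-like receptor pathway, S100A12 and TLR5 (0.34) rose, with 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). S100A12 is the same gene counted above among the classical monocyte markers. Of 18 cytotoxic genes none passed over all genes and 8 fell when adjusted over the list alone. GZMA had a value of -0.61 and PRF1 of -0.37, and the list had an adjusted p = 0.273 with an estimated correlation.

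The fit of only the 10 arrays compared gave 5 higher and 0 lower genes by limma (301 lower at an unadjusted p under 0.05). Leaving out 1 array gave 4 to 22 higher genes, and the count fell to between 4 and 11 without pool 1, 2, 3 or 5 before exercise, pool 1 or 2 at the end of exercise, or pool 2, 3, 4 or 5 at recovery. Lower genes fell to 0 without pool 1 or 3 before exercise (252 and 241 lower at an unadjusted p under 0.05, limma). Of the 15 fits that left out 1 array, the call was lost in 2 for CYP1B1 and CLK4, 3 for HSPH1, 5 for VNN2, 7 for IL2RB and CCR1, 9 for RGS2 and CCR2, 10 for TRIB1 and S100A12, 12 for HLX and 13 for TLR5. CREM, QPCT and FPR1 kept their call in all 15.

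Pool numbers paired the arrays of these 2 groups by the correlation of their deviations. With the pool number as a block, 90 genes were higher and 27 lower. The values, SEs and calls of single genes given above for this comparison came from the fit without the block. With the block, 16 values of named genes gained a call here and 0 lost it, so genes given above as not passing may pass once the pairing is used. Higher genes made up 90.0% of the calls with the deposited scaling, 73.2% after quantile normalization (30 higher, 11 lower) and 78.7% after median centring (37 higher, 10 lower).

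The third comparison asked what changed between the end of exercise and 1 h of recovery. Cytotoxic and NK cell genes fell and monocyte genes rose, and most genes called at the end of exercise were called in the opposite direction here. CLIC3 fell by 2.37 ± 0.14 (log2, SE, 5 arrays per group) and DUSP2 by 2.35 ± 0.15, whereas SGK1, a kinase induced by glucocorticoids and other stimuli, rose by 1.38 ± 0.21. In the limma fit, 352 genes were higher and 578 lower at 1 h of recovery (adjusted p under 0.05). Of the 285 genes higher at the end of exercise, 251 were called lower here, and of the 105 lower genes, 88 were called higher. Both comparisons use the arrays from the end of exercise with opposite sign, which by itself favours such reversals. Simulated unchanged groups gave a median of 0 and at most 11 reversals in 100 draws, and a median covariance of the fold changes of -0.00537 (-0.0205 to 0.00229), against -0.0408 observed. With arrays of the same pool number correlated as observed there were 0 reversals in 100 draws, and the median covariance was -0.00548 (-0.0179 to 0.00155). Independent lists, which leave out the shared arrays, would share 20.2 and 4.54 genes. With the arrays from the end of exercise split between both comparisons, an alternative chosen after seeing the data, the medians over 20 splits were 155 higher genes with 132.5 reversals and 40 lower genes with 20 reversals. The 88 reversals fell to 55, 50 and 58 without pools 3, 4 and 5 before exercise and to 36 and 54 without pools 1 and 4 at the end of exercise.

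The other large falls were those of CD160 (-2.30), AKR1C3 (-2.24), the prostaglandin D2 synthase gene PTGDS (-2.07), KLRF1 (-1.99), PRSS23 (-1.96), the Fas ligand gene FASLG (-1.88) and GZMH (-1.82). The adhesion receptor gene ADGRG1 was also among the 10 largest falls. At recovery AKR1C3 lay at the floor of the scale in pools 4 and 5, and CD160, CLIC3, PRSS23 and FASLG did so in pool 5, so their falls are lower limits and their order is uncertain. Without a floor the values were -2.39 for AKR1C3, -2.36 for CD160, -2.47 for CLIC3 and -2.09 for PRSS23. The other large rises were those of CYP1B1 (1.33), KCNJ2 (1.18), P2RY13 (1.14), QPCT (1.11), MYC (1.02), FPR1 (0.95), IRAK3 (0.94), CCR2 (0.93) and HK3 (0.92). Of 18 cytotoxic genes 15 fell, also when adjusted over the list alone, including GZMB (-1.58) and GNLY (-1.64), with an adjusted p = 0.0827 for the list with an estimated correlation. Of 10 NK cell markers 7 fell, also adjusted over the list alone (adjusted p = 0.0266 with an estimated correlation). Of 7 mature neutrophil markers CXCR2 (-0.95) and FCGR3B (-1.31) fell and CSF3R (0.86) rose, with 2 higher and 2 lower adjusted over the list alone. That list had a mean change of -0.17 ± 0.04 but a median of 0.04, with an adjusted p = 0.685 by camera at the preset correlation, an adjusted p = 0.778 with an estimated correlation and a call down by fry (adjusted p = 0.00814). Of 14 classical monocyte markers 12 rose, also adjusted over the list alone, including S100A9 (0.52) and VCAN (0.51), and the list had an adjusted p = 0.0265 with an estimated correlation. In the IL-1 and Toll-like receptor list 9 of 13 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). TLR5 rose by 0.63, whereas IL18RAP, a receptor chain for interleukin 18, fell by 1.58. Of 11 circadian clock genes 5 fell, also adjusted over the list alone, among them BHLHE40 (-1.16), RORA (-0.72) and DBP (-0.36), with an adjusted p = 0.185 with an estimated correlation. Among heat shock chaperones DNAJB1 fell by 0.99 while HSPH1 (0.68), BAG3 (0.31) and HSPD1 (0.22) rose, with 7 higher and 2 lower adjusted over the list alone (adjusted p = 0.684 with an estimated correlation). The call was lost in 8 of the 15 fits that left out 1 array for HSPD1, 3 for HSPH1 and 1 for BAG3.

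**Figure D2:**
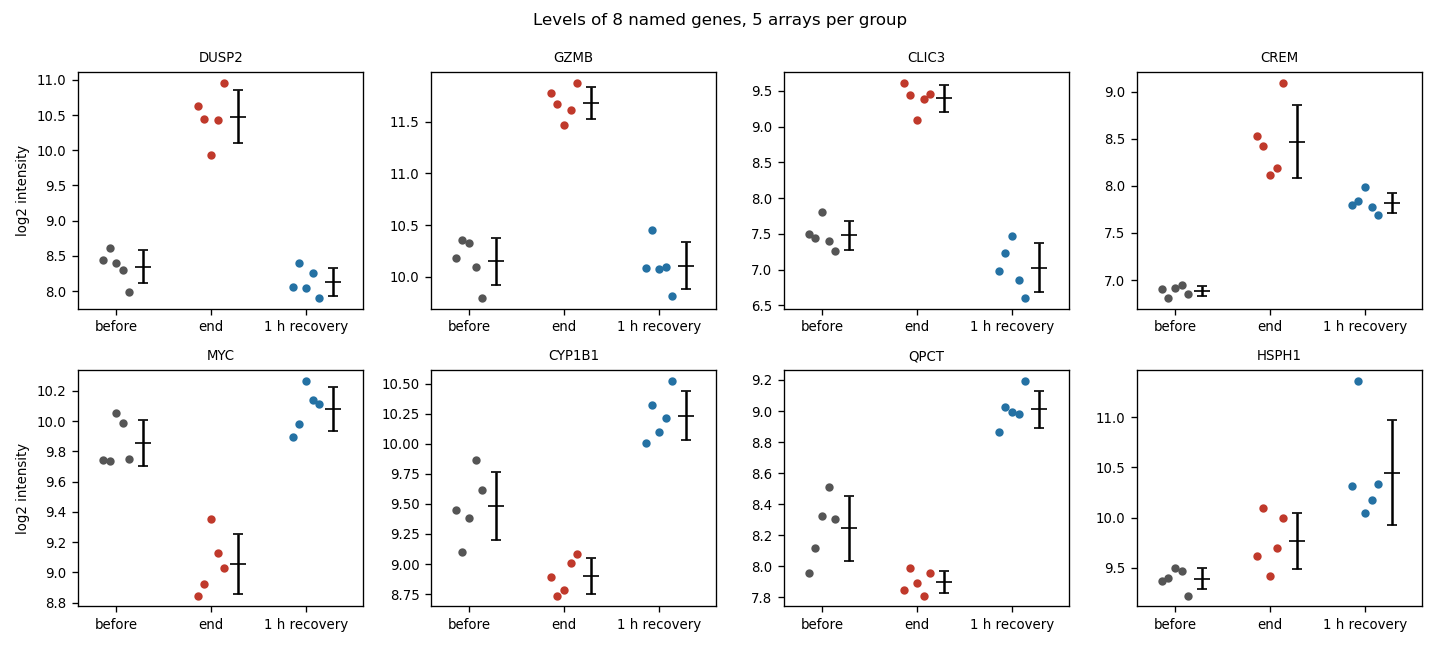
Log2 intensity of 8 named genes in each array (points) with group means and SD (bars), for the 5 arrays of each group. DUSP2 averaged 8.35 before exercise and 10.48 at its end, and CREM was higher than before exercise at both times.

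Against the level before exercise, 1 gene was called in the same direction at both times, which was CREM (1.58, then 0.93). Its levels before exercise (6.81 to 6.94, log2) lay near the floor and below the filter of 7.51. CREM thus passed the filter through its later levels, and the size of its rises is uncertain. IL2RB was higher and then lower, and CCR2, CYP1B1, KCNJ2, QPCT and TLR5 were lower and then higher. KCNJ2 lost its call at recovery in 13 of the 15 fits that left out 1 array, and QPCT its call at the end of exercise in 6. With the pool number as a block 12 genes were called in the same direction at both times, and 5 were after quantile normalization. There were 2 without pool 3 or 4 before exercise, pool 5 at the end of exercise or pool 1 at recovery. For the higher genes 0.63 shared calls would arise between independent lists. The correlation of the log2 fold changes over genes was -0.086 and their covariance -0.0021. Simulated unchanged groups against shared controls gave a median correlation of 0.519 (-0.195 to 0.884) and a median covariance of 0.00611 (-0.00236 to 0.0217), with at most 2 shared calls in 100 draws of independent arrays. With arrays of the same pool number correlated as observed, a simulation chosen after seeing the data, the median correlation was 0.447 (-0.501 to 0.969) and the median covariance 0.00319 (-0.00273 to 0.0107), with 0 shared calls in 100 draws with or without the block. The observed correlation and covariance lay within both simulated ranges, but near their lower ends. A correlation as low came in 2 of 100 draws of independent arrays and 5 of 100 with pool numbers correlated. A covariance as low came in 1 of 100 draws of each. Quantile normalization was not simulated. With the arrays before exercise split between both comparisons, the median correlation over 20 splits was -0.268, the median covariance was -0.0083, and a median of 0 genes were called at both times.

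**Figure D3:**
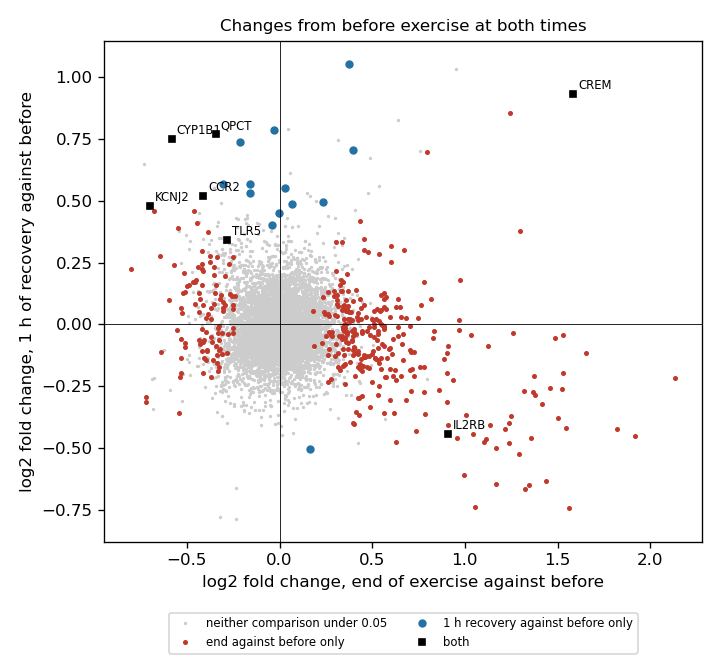
Log2 fold change against before exercise at the end of exercise (x axis) and after 1 h of recovery (y axis) for the 8147 genes tested, coloured by the comparison in which the adjusted p was under 0.05. Of the 7 genes called in both, named in the plot, CREM lies in the upper right quadrant and the other 6 have opposite signs.

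At the preset correlation, adjusted over lists and comparisons together, 10 lists were called up and 6 down at the end of exercise, 10 and 3 at recovery against before exercise, and 8 and 5 at recovery against the end of exercise. Adjusted within each comparison, 16, 13 and 12 of the 33 lists were called. Other splits of the same arrays called up to 19, 18 and 14 lists, so the number of lists called did not stand apart from chance.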

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

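The tests of cell type explanations in this part were chosen after the list results were seen, as were those within pool numbers or with the pool number as a block, while the test without the block of the cell mix behind the heat shock rise and the counts over other splits were set before.

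The rise of NK cell and cytotoxic genes at the end of exercise could come from fewer cells of another type, which would raise all remaining types alike. The NK cell list changed by 0.80 ± 0.08 more than the T cell list (log2, SE). The exact two-sided permutation p = 0.00794 was the smallest possible with 5 arrays per group. This argues against fewer cells of a single type other than T cells as the whole cause. The difference from the T cell list cannot judge fewer T cells, or fewer cells of several types including T cells, since either would itself lower that list. Fewer T cells alone would also raise B cell and classical monocyte markers. Their lists changed by -0.34 ± 0.11 and -0.28 ± 0.07, with 0 of 15 and 0 of 14 tested members positive. For these lists, the values argue against fewer T cells alone as the whole cause. Fewer cells of several types stay open. A larger share of NK cells would raise nearly all their markers. The mean change was 0.70, but 8 of 10 markers had a positive change, and without cell counts a larger share cannot be told apart from a change within cells. For the gene count, 1 of 100 splits of the 10 arrays gave 390 genes, the real one, and the highest other gave 14. Chance is therefore an unlikely source of the count but is not excluded. Among 100 draws of simulated unchanged groups, single draws gave 627, 420 and 1041 genes called in at least 1 comparison, and every other draw at most 2.

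The rise of classical monocyte genes at 1 h of recovery could come from neutrophils left in the preparation. The mature neutrophil list changed by -0.25 ± 0.06 relative to the monocyte list. The difference was -0.17 ± 0.05 without FCGR3B, whose probe set can share signal with FCGR3A of NK cells and whose removal was chosen last. For the 7 markers tested, this would argue against neutrophils as the whole cause only if the markers followed neutrophils alone. CXCR2, which was kept, changed by 0.97 at the end of exercise and by -0.95 from there to recovery, and the NK cell list by 0.70 and -0.96. CSF3R moved the other way (-0.45, then 0.86). A fall of NK cell signal could thus lower the neutrophil list, so neutrophils stay open. The neutrophil list is also a limited probe, since CXCR2 (7.57) and KCNJ15 (7.65, log2 before exercise) lay close to the filter of 7.51. CSF3R changed by 0.41, FCGR3B by -0.41 and the other markers by 0.02 to 0.14. The immature granule list had a mean change of 0.26 ± 0.18. A smaller share of NK cells would raise B and T cell markers alike, and the monocyte list rose by 0.44 ± 0.08 more than their mean, which argues against that as the whole cause. Within pool numbers, which pair these groups, each of these 3 differences between lists had its sign in 5 of 5 pairs (SE 0.023, 0.017 and 0.030). The exact two-sided sign-flip permutation p = 0.0625 for each was the smallest that this test allows. Over splits of the arrays that ignore pairs, the exact permutation p = 0.00794, 0.0159 and 0.00794. A larger monocyte share, as a response to exercise, stays open.

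The rise of heat shock chaperones at 1 h of recovery could follow from a shift in cell mix. The recovery effect was 0.35 ± 0.10 without and 0.31 ± 0.13 with the NK cell and monocyte scores as covariates, over 2 standard errors from 0 as set beforehand. That bound left out the pairing: with the pool number as a block the effect with covariates was 0.08 ± 0.18, where 2 standard errors either way hold both 0 and 0.35, so a shift in cell mix stays open. Without the block it was also within 2 standard errors of 0 without pool 5 before exercise (0.27 ± 0.14), pool 5 at the end of exercise (0.22 ± 0.15) or pool 1 at recovery (0.32 ± 0.17). Blood handling or time of day cannot be told apart from exercise, since no unexercised donors were measured beside the change of 0.35.

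Pool numbers pair the arrays of 1 h of recovery and before exercise. Among the 16 splits that part all 5 pairs, the real one gave 20 genes and the highest other 0, so 1 reached the real count, but 16 splits are too few for a share under 0.05. Among 100 splits drawn without regard to pairs, 2 gave at least the real 20. The highest other gave 81, over 4 times as many, and set pools 1 and 5 against pools 3 and 4 of both groups, with pool 2 divided, which points to a structure of the samples by pool number. For 1 h of recovery against the end of exercise, 1 of 100 splits gave the real 930, and the highest other gave 101. Chance is unlikely there, with the limit from the simulated unchanged groups given above. For the number of lists called at the preset correlation chance cannot be excluded: 5, 7 and 8 of 100 splits gave as many as the real 16, 13 and 12 (adjusted within each comparison), and the highest others gave 19, 18 and 14.

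Single arrays stood far from the other 4 of their group in 5 of 99 list scores and 20 of 329 levels of named genes, where chance gives about 1 in 20. The gap, as a share of the range, was 0.757 for dendritic cells at the end of exercise and 0.843 for basophils and eosinophils before exercise. At recovery it was 0.791 for heat shock chaperones, 0.712 for immediate early genes and 0.817 for glucocorticoid-induced genes. Before exercise it was 0.772 for ADGRG1, 0.873 for AKR1C3, 0.727 for CCR1, 0.724 for CST7, 0.784 for HLX, 0.780 for LCK, 0.758 for PDGFB and 0.719 for TCL1A. At the end of exercise it was 0.764 for ADGRG1 and 0.713 for CTSS. At recovery it was 0.732 for CCR7, 0.752 for CD14, 0.729 for CD160, 0.784 for HSPH1, 0.786 for LEF1, 0.776 for NDUFA9, 0.711 for NDUFS1, 0.791 for PRF1, 0.786 for PSMC4 and 0.727 for STIP1.

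Genes called in opposite directions at both times differed between them by 0.93 for CCR2, 1.33 for CYP1B1, -1.35 for IL2RB, 1.18 for KCNJ2, 1.11 for QPCT and 0.63 for TLR5 (log2, recovery minus end, limma adjusted p under 0.05). The lists that did so differed by -0.96 for NK cells, -1.19 for cytotoxic genes, 0.59 for classical monocytes and 0.34 for the IL-1 and Toll-like receptor pathway, by calls at the preset correlation. With an estimated correlation none of these 4 lists was called at both times: the adjusted p at the end of exercise and at recovery was 0.0265 and 0.173 for NK cells, 0.0827 and 0.273 for cytotoxic genes, 0.104 and 0.0265 for monocytes, and 0.333 and 0.132 for the pathway. Among 1701 probe sets without a single gene, 53, 2 and 121 passed the test in the 3 comparisons.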

How the results depend on the processing

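The cause of the differences below was not tested. For the end of exercise against before exercise (285 higher, 105 lower), the lower genes numbered 196 after quantile normalization, 167 after median centring, 159 over every probe set, 223 with the pool number as a random effect and 64 at an unadjusted p under 0.001. Array weights gave 450 higher and 229 lower. With the pool number as a replicate block there were 456 higher and 288 lower, and for 1 h of recovery against the end of exercise 532 higher and 825 lower. In those comparisons 7 and 5 of 10 arrays correlated best with their own number. The block changed the call of 1 list, red cells at the end of exercise (adjusted p = 0.0479). For recovery against end (352 higher, 578 lower), every probe set gave 529 higher, and an unadjusted p under 0.001 gave 217 and 337.

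For 1 h of recovery against before exercise (18 higher, 2 lower), quantile normalization gave 30 and 11, median centring 37 and 10, no filter 4 and 1, and the fit of only the 10 arrays compared 5 and 0. In that last fit limma put 301 lower genes at an unadjusted p under 0.05. The block gave 90 and 27, the random effect 48 and 17, and an unadjusted p under 0.001 gave 45 and 17. The mean of probe sets and every probe set each gave 5 lower genes.

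With an estimated correlation 1 list was called up and 0 down at the end of exercise, 2 and 0 at recovery against before, and 1 and 1 at recovery against end. By fry, 2 lists were down at the end of exercise, 4 up and 0 down at recovery against before, and 3 up at recovery against end, where quantile normalization left 3 down. Calls at both times in the same direction (1) numbered 5 after quantile normalization, 12 with the block and 0 with the arrays before exercise split.

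Reversals from the end of exercise to recovery (251 of higher and 88 of lower genes) were recounted under alternatives chosen after seeing the counts. They numbered 379 and 219 with the replicate block and 132.5 and 20 with the arrays at the end of exercise split. Those of lower genes numbered 155 after quantile normalization, 136 after median centring, 56 with no filter, 169 with the random effect, 159 with array weights and 44 at an unadjusted p under 0.001. Leaving out each array gave 181 to 272 and 36 to 104.

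Leaving out each array gave 194 to 366 higher and 46 to 126 lower genes for the first comparison, 4 to 22 and 0 to 3 for the second, and 249 to 362 and 387 to 686 for the third. Lower genes at the end of exercise fell to 68 and 60 without pools 3 and 4 before exercise and to 46 without pool 1 at the end. Higher genes at recovery against before fell to 4, 5, 10 and 7 without pools 1, 2, 3 and 5 before exercise, to 11 and 10 without pools 1 and 2 at the end, and to 5, 6, 9 and 10 without pools 2, 3, 4 and 5 at recovery. Lower genes there fell to 0 without pool 1 or 3 before exercise. Lists up at recovery against end fell to 5 without pool 2 at the end, and lists down to 3 without pool 1 or 5 at the end or pool 5 at recovery. Lists up and down ranged from 10 to 11 and 5 to 7, 8 to 11 and 2 to 4, and 5 to 8 and 3 to 6, and shared calls from 1 to 2.

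Among values of named genes under all alternatives, 5664 kept their direction and side of the threshold, 308 lost the call and 132 gained it. Those that changed sign were CIITA at recovery against end with the mean of probe sets (0.033) and PDGFB at recovery against before without pool 4 before exercise (-0.025, against 0.34 at most without another array), neither called. Genes near the floor have understated changes.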

Other observations

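Several fixed lists not described above were called at the preset correlation and not with an estimated one. At the end of exercise oxidative phosphorylation (32 genes, median 0.11, adjusted p = 0.684 with an estimated correlation), proteasome (22 genes, 0.15, adjusted p = 0.618) and the unfolded protein response (16 genes, 0.14, adjusted p = 0.618) were called up, with XBP1 (0.57) the member that rose. Adrenergic and cAMP signalling was also called up, with CREM and PRKACB (0.46) rising among 13 genes (adjusted p = 0.262 with an estimated correlation, and adjusted p = 0.00816 by fry, which also called it up), and MHC class II presentation down, with CTSS (-0.27), HLA-DMB (-0.37) and HLA-DRA (-0.31) falling among 11 (adjusted p = 0.313). At 1 h of recovery against before exercise platelets (15 genes, median 0.14, adjusted p = 0.618 with an estimated correlation) and glycolysis and hypoxia response (21 genes, 0.07, adjusted p = 0.314) were called up with no member past the test. The same held for immediate early genes (24 genes, median 0.08, adjusted p = 0.27), antioxidant and iron storage genes (16 genes, 0.06, adjusted p = 0.544), growth factors (11 genes, 0.07, adjusted p = 0.149) and immature neutrophil granule genes (6 genes, 0.27, adjusted p = 0.51). NK cell markers (10 genes, median -0.18, adjusted p = 0.173) and B cell markers (15 genes, -0.21, adjusted p = 0.57) were called down, again with no member past the test. At the end of exercise the call was lost in 7 of the 15 fits that left out 1 array for HLA-DRA, 6 for XBP1, 5 for HLA-DMB and 2 for PRKACB.

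From the end of exercise to 1 h of recovery, CCR7 (0.42) and NELL2 (0.39) rose among 10 genes of naive and central memory T cells (adjusted p = 0.104 with an estimated correlation, and adjusted p = 0.00185 by fry, which called the list up). CTSS (0.39), HLA-DMB (0.44) and HLA-DRA (0.28) rose among 11 genes of MHC class II presentation (adjusted p = 0.486), and TCL1A (0.42) among 15 B cell markers (adjusted p = 0.684). HLA-DRA lost its call in 7 of the 15 fits that left out 1 array and TCL1A in 1. Called with no member past the test were oxidative phosphorylation (median -0.11) and proteasome (-0.11), both down, and platelets (0.19), up, each with an adjusted p = 0.774. Immature neutrophil granule genes were called up (0.33, adjusted p = 0.618).

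Lists with no call in any comparison included cytosolic ribosomal proteins, with a median change of 0.01 at the end of exercise over 26 genes, interferon-stimulated genes (0.01 over 22 genes) and proliferation (0.04 over 16 genes). Of the interferon-stimulated genes none passed the test at the end of exercise or at 1 h of recovery against before exercise.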
